A study of Homo sapiens with 4 samples.

How the data were processed

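Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in MCF-7, an established human breast cancer cell line that expresses the estrogen receptor. Per the labels' protocols, the cells were kept in low glucose medium with serum stripped of steroids and were given dioxin at 10 nM for 45 min. The aryl hydrocarbon receptor (AHR) is a transcription factor that dioxin activates. ARNT is the partner protein with which AHR binds DNA. Each was pulled down with its own antibody, and rabbit IgG served as the negative control. Per the labels' protocols, the recovered DNA went through whole-genome amplification before the sequencing libraries were made. Amplification can change the relative abundance of fragments, and the lists cannot show how much.

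The labels describe 4 samples, each a pool of replicates. The AHR sample pooled replicates 1 and 3, and the ARNT sample pooled replicates 1 and 2. The 2 IgG samples pooled replicates 1 and 3 and replicates 1 and 2. Processed lists were analysed here for the AHR and the ARNT sample only, so each list was 1 sample, without a replicate check. The values of the single replicates and of the IgG pools were not analysed here. No untreated or vehicle sample was analysed either, so the lists describe where AHR and ARNT were bound under dioxin, not what dioxin changed.

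Each list gave chromosome, first and last position, a running number, a score and a strand per bound region. Per the file headers, each list came from the pooled antibody sample set against the IgG pool of the same replicate numbers, with a false discovery rate label of 1 for AHR and 5 for ARNT, read here as percent. The ARNT list was thus filtered less strictly. The submitters' processing notes name CASAVA and the genome build hg19. The peak caller and aligner are not given in the sources used here. Positions lay on a grid of 50 bp in the deposited files, and the first and last positions were both counted as part of a region. The deposited score was 1000 in every line of both lists and so carried no measurement. The running number followed the order of the lines, and nothing in the sources used here says what the order stands for. It is called the list number below. One line of the ARNT list held decimal numbers in place of a chromosome and a list number and was left out, which left 1352 regions. The lists hold no read counts, so the depth behind a region is unknown.

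Because no score could rank regions, the comparisons that were planned on scores used region width and list number, a choice made after the scores had been seen. The planned comparisons with gene positions, promoters, gene lists and DNA motifs were not run, because no genome or annotation of hg19 was used here. For that reason regions are given by position, without gene names. The rule for named regions, set before the data were examined, took those with the highest score or, if no column held a score, the widest. The constant score was treated as no score once it had been seen. The rule then gave the 10 widest regions of each list and the 10 overlapping pairs with the smallest sum of width ranks. Ties were broken by chromosome and position. Other regions named are said to have been chosen after their values were seen.

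An AHR and an ARNT region were called shared where they had at least 1 bp in common. To obtain the overlap that chance gives, every ARNT region was placed at random on its own chromosome, within the span from the first to the last region of either list, in 10000 draws. The span includes sequence in which reads cannot be placed, so this expectation is low. A closer expectation came from moving each ARNT region by up to 100 kb either way, also in 10000 draws. Overlap p-values were one-sided, and 1e-04 is the smallest that 10000 draws can give. Medians of shared and unshared regions were compared within each list by a two-sided permutation test with 100000 resamples, for which the smallest p-value is 1e-05. Correlations across regions or chromosomes used the same number of permutations. Regions of one list are not independent replicates, and their p-values describe these 2 lists only. Counts per chromosome were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 chromosomes. Intervals of shares are Wilson 95% intervals and cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

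The overlap procedure was tested on simulated data in which 300 of the 1352 ARNT regions were centred on AHR regions and the rest were placed at random. All 300 were found, with 1 chance overlap beside them. Of 200 lists placed wholly at random, 3 gave an overlap p-value under 0.05. Regions centred on AHR regions must overlap them, and the random lists were placed in the same way as the expectation. In the real lists regions lay nearer one another than random placement gives, which the simulation left out. It therefore checks the counting, not the p-values of the real lists. Other definitions of sharing were tried: an overlap of at least 50% of both regions, centres within 100 bp, and a gap of at most 1 kb. Alternatives added after seeing the data took the earlier 50% or the wider 50% of each list, or cut the AHR list to the length of the ARNT list by order or by width. Counts per chromosome were also compared between the unshared regions of the lists, so that no region was in both counts, likewise after seeing the data. The alternatives, and the tests of widths in dense windows, used 1000 placements or 20000 resamples, except the displacement by up to 100 kb.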

Results

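Binding of AHR and of its partner ARNT was mapped by ChIP-seq across the genome of MCF-7 breast cancer cells given dioxin at 10 nM for 45 min. The design named 3 groups, an AHR sample, an ARNT sample and 2 IgG controls, each sample pooling 2 replicates. The lists of bound regions of the AHR and the ARNT sample were analysed. The AHR list held 2594 regions and the ARNT list 1352 regions. Both covered all 22 autosomes and chromosome X. AHR regions covered 1822 kb in all and ARNT regions 758 kb. Without replicates or read counts per region, no error can be put on the strength of binding at a single region, and the comparisons below concern positions, widths and the order of the deposited lists.

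AHR regions were wider than ARNT regions. The median width was 650 bp for AHR (quartiles 500 and 800 bp, range 200 to 3000 bp, n = 2594 regions) and 500 bp for ARNT (quartiles 450 and 650 bp, range 150 to 1800 bp, n = 1352 regions). The lists were filtered at different false discovery rates, and the width of a called region also moves with signal and depth, so the width difference was not tested as a difference in binding. Within each list, regions nearer the top were wider. In the AHR list the median width fell from 850 bp in the first 259 regions to 550 bp in the last 259. In the ARNT list it fell from 650 bp in the first 135 regions to 450 bp in the last 135. Across regions, width and list number had a Spearman rho of -0.40 in the AHR list and -0.39 in the ARNT list (permutation p = 1e-05 for each). Pearson's r was -0.38 and -0.36 (permutation p = 1e-05 for each).

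Of the 10 widest AHR regions, 9 overlapped an ARNT region, and 3 lay on chromosome 20. The widest of all spanned 3000 bp, from 52480400 to 52483399 on chromosome 20 (hg19), and was the exception without an ARNT partner. The next, 2750 bp from 46618500 to 46621249 on chromosome 20, overlapped an ARNT region of 1250 bp. An AHR region of equal width from 51961100 to 51963849 on the same chromosome overlapped an ARNT region of 1550 bp that was number 5 in its list. On chromosome 16, the AHR region from 87822300 to 87824849 (2550 bp) contained an ARNT region of 1050 bp. AHR regions of 2050 bp each lay at 65483350 to 65485399 on chromosome 6, at 69765000 to 69767049 and 91899800 to 91901849 on chromosome 8, and at 75017450 to 75019499 on chromosome 15. Those at 103981100 to 103983099 on chromosome 5 (2000 bp) and 100477800 to 100479749 on chromosome 14 (1950 bp) completed the group. Their list numbers ran from 25 to 1094, so the widest regions were not those at the head of the list.

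All of the 10 widest ARNT regions overlapped an AHR region. The widest spanned 1800 bp, from 226982500 to 226984299 on chromosome 2, and its centre coincided with that of an AHR region of 1500 bp. It was followed by a region of 1750 bp at 74934350 to 74936099 on chromosome 15, whose AHR partner of 1900 bp was number 2 in the AHR list. Chromosome 20 held a region of 1600 bp at 50351300 to 50352899 and one of 1550 bp at 51961950 to 51963499. The others lay on chromosome 21 (43476150 to 43477649, 1500 bp), chromosome 10 (29393650 to 29395099, 1450 bp), chromosome 15 (75017900 to 75019299, 1400 bp), chromosome 3 (8497700 to 8499049, 1350 bp), chromosome 8 (119890600 to 119891949, 1350 bp) and again chromosome 15 (51658900 to 51660249, 1350 bp). Chromosome 15 thus gave 3 of the 10.

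The 10 pairs with the smallest sum of width ranks were led by the pair at 51961100 to 51963849 on chromosome 20, where the AHR region ranked 3 and the ARNT region 4 by width. The pairs starting at 74934250 and 75017450 on chromosome 15 came next, with AHR ranks of 11 and 8 and ARNT ranks of 2 and 7. The remaining pairs had their AHR regions at 46618500 to 46621249 on chromosome 20, 51658700 to 51660499 and 101261150 to 101262749 on chromosome 15, 43475950 to 43477649 and 16571750 to 16573449 on chromosome 21, 226982650 to 226984149 on chromosome 2, and 8497750 to 8499299 on chromosome 3. In these 7 pairs the AHR regions were 1500 to 2750 bp wide and the ARNT regions 1250 to 1800 bp wide.

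**Figure D1:**
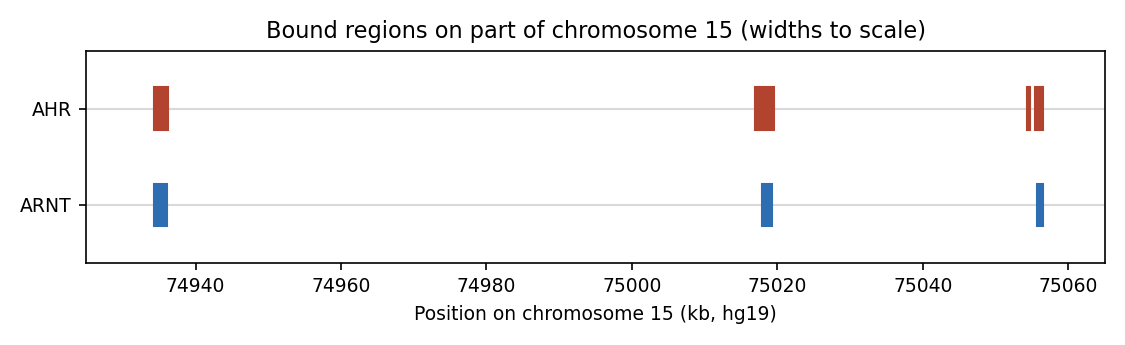
Bound regions of the AHR and ARNT lists on part of chromosome 15, with position in kb (hg19) on the horizontal axis and 1 row per list; boxes are drawn to scale. The 3 ARNT regions shown each lie within an AHR region; the AHR box that ends at 75019499 is drawn as 1 block but holds 2 regions with a gap of 50 bp.

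The first question of the design was how far the places bound by AHR and by ARNT coincide. Of the 2594 AHR regions, 884 overlapped an ARNT region, or 34.1% (95% interval 32.3 to 35.9%). Of the 1352 ARNT regions, 890 overlapped an AHR region, or 65.8% (63.3 to 68.3%). The contrast between the 2 shares follows from the lengths of the lists, since the shared counts of 884 and 890 are nearly the same. With the AHR list cut to its first 1352 regions, a setting chosen after seeing the data, 51.9% of AHR and 52.4% of ARNT regions were shared. Lists of equal length must give nearly equal shares here, so the cut shows the level of sharing only. In the full lists, sharing left 1710 AHR regions and 462 ARNT regions without a partner in the other list. The 890 overlapping pairs included 6 AHR regions that each covered 2 ARNT regions.

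Random placement of the ARNT regions on their chromosomes gave 1.72 ± 1.32 overlapped AHR regions (mean ± SD of 10000 draws) and at most 9, against the 884 observed (permutation p = 1e-04, one-sided, the smallest possible). The observed number was 513 times the random mean. When ARNT regions were moved by no more than 100 kb, 14.3 ± 3.80 AHR regions were overlapped and at most 29, so that the observed number was 61.6 times this closer expectation (permutation p = 1e-04). Seen from the ARNT list, the 890 shared regions stood against 14.2 ± 3.75 after the same displacement, a ratio of 62.6 (permutation p = 1e-04). Neither placement follows where regions of any kind tend to be called, and no unrelated list was compared. The ratios therefore do not separate joint binding from places at which both antibodies gave regions for another reason. A displaced region can also stay on its own partner, so the closer expectation is not free of the observed overlap.

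Shared regions were centred at nearly the same position in both lists. The median distance between the centres of a pair was 50 bp (quartiles 25 and 100 bp, maximum 1125 bp, n = 890 pairs), which is the size of 1 step of the position grid. The centres lay within 100 bp of each other in 710 pairs (79.8%). The median signed distance was 0 bp. In 645 pairs (72.5%) the ARNT region lay wholly within the AHR region, and in 131 pairs the AHR region lay wholly within the ARNT region, pairs with the same ends counting in both. The AHR region was the wider one in 674 pairs, the ARNT region in 116, and the widths were equal in 100. Overlap alone limits how far apart the centres of a pair can lie. No expected distance or containment for overlapping regions of these widths was computed.

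Shared regions stood earlier in both lists and were wider than unshared ones. In the AHR list the median list number was 629.5 for the 884 shared and 1611.5 for the 1710 unshared regions (permutation p = 1e-05, two-sided). Their median widths were 750 bp (quartiles 600 and 950 bp) and 600 bp (500 and 750 bp), a difference of 150 bp (permutation p = 1e-05). In the ARNT list the median list number was 518 for the 890 shared and 940.5 for the 462 unshared regions (permutation p = 1e-05). The ARNT widths were 550 bp (500 and 700 bp) and 400 bp (350 and 500 bp), again 150 bp apart (permutation p = 1e-05). With sharing defined by centres within 100 bp, the width difference shrank to 50 bp in the AHR list (permutation p = 0.00475) and 100 bp in the ARNT list (permutation p = 5e-05).

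**Figure D2:**
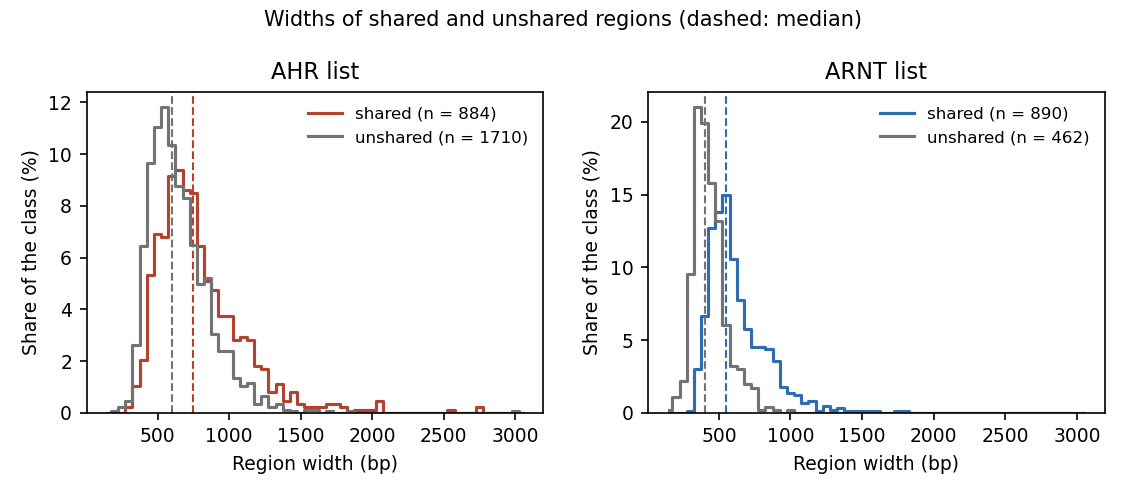
Widths in bp of shared (coloured) and unshared (grey) regions of the AHR list and of the ARNT list, as the percent of each class per 50 bp step; dashed lines mark medians. Shared regions have medians of 750 and 550 bp and unshared ones of 600 and 400 bp, and the distributions overlap widely.

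The share of AHR regions with an ARNT partner fell along the AHR list. It was 81.1% in the first 259 regions (95% interval 75.9 to 85.4%), 28.8% in numbers 1038 to 1297 (23.7 to 34.6%) and 10.8% in the last 260 (7.56 to 15.1%). The share of ARNT regions with an AHR partner was 97.0% in the first 135 regions (92.6 to 98.8%) and 37.5% in the last 136 (29.8 to 45.9%). Only 4 of the first 135 ARNT regions had no AHR partner, compared with 49 of the first 259 AHR regions. These 2 numbers are not on the same footing, because the AHR list was the longer one and more strictly filtered. Each list's head was almost wholly shared: 9 of the first 10 AHR regions and 10 of the first 10 ARNT regions had a partner.

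**Figure D3:**
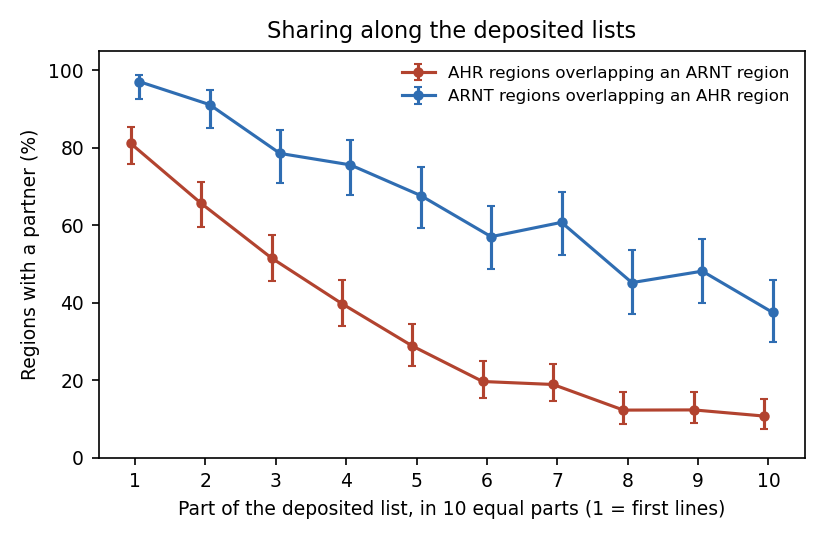
Percent of regions that overlap a region of the other list (vertical axis), in 10 successive parts of the AHR and the ARNT list in deposited order (horizontal axis); bars are Wilson 95% intervals of counting error. Sharing falls from 81.1% to 10.8% along the AHR list and from 97.0% to 37.5% along the ARNT list.

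Some regions near the head of the lists, chosen after their values were seen, show both outcomes. The first AHR region, at 99439950 to 99440999 on chromosome 15, overlapped ARNT region number 23 with coinciding centres. The first ARNT region, at 5786950 to 5788099 on chromosome 17, overlapped AHR region number 4. AHR region number 7, at 6034750 to 6035899 on chromosome 7 (1150 bp), had no ARNT partner and was the earliest such region. Those that followed were number 36 at 72963100 to 72963849 on chromosome 16 and number 39 at 122186150 to 122187199 on chromosome 12. The earliest ARNT region without an AHR partner was number 78, at 57184100 to 57184549 on chromosome 17 (450 bp).

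The order and the widths of shared regions were related between the lists. Over the 890 pairs, the list numbers had a Spearman rho of 0.42 and a Pearson r of 0.37 (permutation p = 1e-05 for each). The widths had a Spearman rho of 0.61 and a Pearson r of 0.58 (permutation p = 1e-05 for each). These relations are across regions within 1 pooled sample per antibody, and regions are not independent replicates. A pair that departed from the relation was at 75017450 to 75019499 on chromosome 15. Its regions ranked 8 and 7 by width in the AHR and ARNT lists, while their list numbers were 496 and 1349, the latter close to the end of the list of 1352.

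Over whole lists, the planned comparison found no chromosome that held a different share of the AHR and the ARNT list (Fisher's exact test, smallest unadjusted p = 0.059, on chromosome X; 0 of 23 chromosomes had an unadjusted p under 0.05). Shared regions are in both lists, so the counts compared are not independent, which works against finding a difference. Among the regions without a partner, compared after the data were seen, chromosome X did differ, with 42 of 1710 AHR regions (2.46%) and 28 of 462 ARNT regions (6.06%; Fisher's exact test, adjusted p = 0.00661), and no other chromosome passed adjustment. This difference no longer passed when sharing required centres within 100 bp (Fisher's exact test, adjusted p = 0.0685), in the earlier 50% of each list (Fisher's exact test, adjusted p = 0.338) or in the wider 50% (Fisher's exact test, adjusted p = 0.902). The log2 ratio of the ARNT to the AHR share was 1.015, 1.37 and 0.723 in these settings, against 1.303. The earlier and the wider 50% left only 8 and 5 unshared ARNT regions on chromosome X, in place of 28. Density varied between chromosomes. Per Mb of the span covered by the lists, chromosome 21 had 1.66 AHR and 1.16 ARNT regions, chromosome 15 had 1.59 and 0.99, and chromosome 20 had 1.499 and 0.864. At the other end, chromosome X had 0.39 AHR and 0.30 ARNT regions, chromosome 18 had 0.40 and 0.23, and chromosome 4 had 0.44 and 0.22. The overall densities were 0.90 and 0.47 per Mb.

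In another comparison added after the data were seen, which counts the same 28 unshared ARNT regions, chromosome X stood apart in how many of its ARNT regions were shared. There, 17 of 45 ARNT regions overlapped an AHR region, or 37.8% (95% interval 25.1 to 52.4%), against 66.8% on all other chromosomes (Fisher's exact test, adjusted p = 0.00361). Chromosome 18 had 6 of 18 ARNT regions shared, or 33.3% (16.3 to 56.3%), which did not pass adjustment (Fisher's exact test, adjusted p = 0.0597). Among AHR regions the shared fraction was 28.8% on chromosome X (17 of 59) and did not differ from the rest after adjustment (Fisher's exact test, adjusted p = 0.934). The chromosome X difference no longer passed the threshold when sharing required centres within 100 bp (31.1% against 53.3%, Fisher's exact test, adjusted p = 0.086). It was also lost in the earlier 50% of each list, with 21 regions on chromosome X (61.9% against 71.5%, Fisher's exact test, adjusted p = 0.80), and in the wider 50%, with 11 (54.5% against 69.0%, Fisher's exact test, adjusted p = 0.921).

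**Figure D4:**
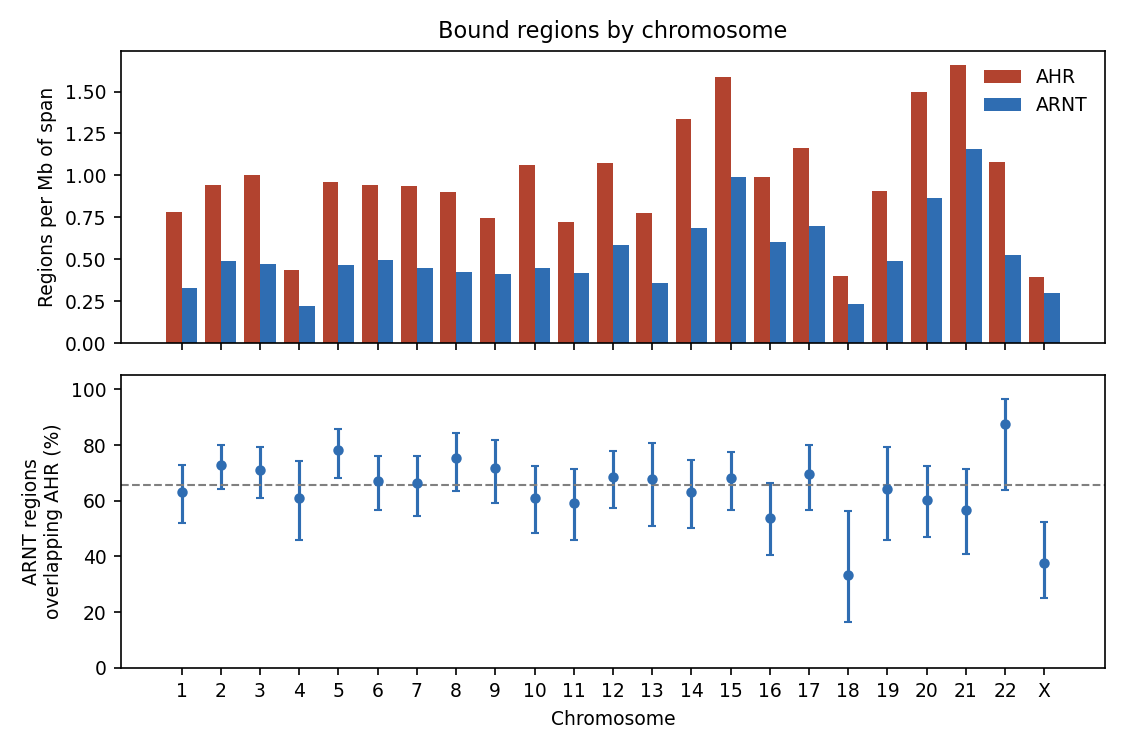
Upper panel: AHR (red) and ARNT (blue) regions per Mb of the span covered by the lists, by chromosome. Lower panel: percent of ARNT regions that overlap an AHR region, with Wilson 95% intervals; the dashed line is the value of 65.8% for the whole list, and chromosome X lies at 37.8%.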

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

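Of 53 values recomputed under other settings, 46 were labelled as the same. Tested values had to keep their side of the threshold, and counts had to stay within 1.5 times the original. A tested value could thus change in size and keep the label. Over the settings, the Spearman rho of pairs ran from 0.29 to 0.44 for list numbers and from 0.49 to 0.715 for widths. The overlap tests lay so far past the threshold that their label was hardly in doubt. The median centre distance had to stay within 1 SD of the distances over pairs, a wide limit. None was labelled as reversed, but that label was open only to differences, correlations and log2 ratios, not to shares, counts or distances. All 7 exceptions concern chromosome X or the count of chromosomes that differ between the lists, which rose from 0 to 1, chromosome X, when only regions without a partner were compared. The other 6 kept their direction and were no longer past the threshold. With centres within 100 bp, in the earlier 50% and in the wider 50% of each list, the ARNT regions on chromosome X that overlap an AHR region were 31.1%, 61.9% and 54.5%, and among unshared regions the log2 ratio of the ARNT to the AHR share on chromosome X was 1.015, 1.37 and 0.723, against 1.303. The last 2 settings left 21 and 11 ARNT regions on the chromosome in place of 45, of which 8 and 5 were unshared in place of 28. All settings for chromosome X were chosen after seeing the data. The shares of AHR regions with a partner ran from 27.4% (centres within 100 bp) to 35.1% (gap of at most 1 kb) over the definitions of sharing, and those of ARNT regions from 52.5% to 66.3%. Cutting the AHR list to its first 1352 regions, a setting chosen after seeing the data, gave 51.9% of AHR and 52.4% of ARNT regions shared. Cutting it to its widest 1352 gave 43.6% and 44.1%. That the 2 shares come out nearly equal is fixed by the equal lengths and is not a finding. The ratio of observed to random overlap depended on how the random regions were placed, 513 for AHR regions with placement on the whole chromosome and 61.6 with a displacement of up to 100 kb, and on the definition of sharing: 1476 with 50% of both regions, 2536 with centres within 100 bp and 208 with a gap of at most 1 kb. Shortened lists gave 554.5 to 928.2. Settings by score could not be run, since the score was constant, and those with promoters, motifs and gene lists were not run. No paired analysis was possible because each list was made from pooled replicates. Depth per region is unknown, so the lists cannot say how far a missing partner lay under the threshold.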

Other observations

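The tests within the first 259 AHR regions and those of list position and AHR density for chromosome X were set before their results were seen. Chromosome X itself was picked after seeing the data. The tests on chromosome X by part of the list, on dense windows, on neighbouring regions and on density over chromosomes were chosen after seeing the data.

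Regions of each list lay near one another more often than random placement gave. In the AHR list, 443 of 2594 regions (17.1%) had another AHR region within 10 kb, against 53.6 ± 10.1 after random placement (permutation p = 1e-04). In the ARNT list it was 130 of 1352 regions (9.62%) against 14.8 ± 5.42 (permutation p = 1e-04). Any gap up to 10 kb counted, so a site called in several parts counts as neighbours and adds to the windows below. On chromosome 15, for example, an AHR region ended at 75017399 and the next began at 75017450. How many neighbours are parts of the same site was not tested. The span for random placement includes sequence in which reads cannot be placed, so the random expectations here are low. The densest stretch of 5 Mb in both lists was 45 to 50 Mb on chromosome 20, with 29 AHR and 18 ARNT regions. The fullest stretch in 10000 random placements held 22 AHR or 16 ARNT regions (permutation p = 1e-04 for each). The densest single Mb in both lists was 101 to 102 Mb on chromosome 7, with 11 AHR and 10 ARNT regions against random maxima of 10 and 9 (permutation p = 1e-04 for each). Of these, 8 in each list were shared.

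A minority of the regions without a partner, but more than random placement gave, lay near regions of the other list. The random expectation is again low, for the same reason. Some of these regions may be parts of a shared site. Allowing a gap of at most 1 kb raised the shared fraction from 34.1% to 35.1% of AHR and from 65.8% to 66.3% of ARNT regions. Of the 462 unshared ARNT regions, 37 (8.01%) lay within 10 kb of an AHR region, against 8.61 ± 2.92 after random placement (permutation p = 1e-04). Of the 1710 unshared AHR regions, 148 (8.65%) lay within 10 kb of an ARNT region, against 17.3 ± 4.14 (permutation p = 1e-04). Unshared AHR and unshared ARNT regions, which have no region in common, also followed each other in density over 23 chromosomes (Spearman rho 0.64, permutation p = 0.00124; Pearson r 0.72, permutation p = 9e-05). Without the 2 chromosomes farthest from the median AHR density, r was 0.55. Both densities are counts divided by the same chromosome spans, which can by itself relate them, and the permutation does not remove this. The relation therefore does not show a link between AHR-only and ARNT-only binding. Both lists together gave a rho of 0.92 (permutation p = 1e-05), part of which comes from shared regions. With 2 relations tested, the adjusted p-values are 0.00124 and 2e-05 (permutation).

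The first pattern weighed is that unshared regions stood late in the lists. A candidate explanation is that many of their partners were bound but fell under the threshold of the other list. The 49 unshared AHR regions among the first 259 also stood later there than the 210 shared ones. Their median list number was 60.5 higher, 179 against 118.5 (permutation p = 0.00117), while their widths of 750 and 900 bp did not pass the threshold (permutation p = 0.0566). This repeats the fall of sharing along the whole list and so does not support the explanation. Partners under the threshold and weaker sites bound by AHR without ARNT cannot be told apart, since both give this order. The false discovery rate labels also allow for some regions called in error, and the order does not separate these from either. Only the head of the AHR list was tested, so unshared ARNT regions were not covered. No test here measured ARNT signal under the threshold, and the reading assumes that list order follows strength.

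The second pattern is the dense window on chromosome 20. A gain in copy number of the segment in MCF-7 cells could raise the signal there, and it predicts regions wider than others of their shared or unshared class. In the ARNT list they were 225 bp wider (permutation test, adjusted p = 0.003 over 4 tests), and in the AHR list 100 bp wider, which did not pass (permutation test, adjusted p = 0.162). In the window on chromosome 7 the differences were 150 bp for ARNT (permutation test, adjusted p = 0.0733) and -50 bp for AHR (permutation test, adjusted p = 0.743). The prediction was written after the data were seen, so no width here is an independent test of it. The adjustment covers these 4 tests, not the other dense windows whose widths were also compared. The window on chromosome 20 is a fixed stretch, and wide regions beyond 50 Mb there counted as elsewhere. Regions were called against IgG pools, and how far that offsets a gain was not tested. The values for ARNT on chromosome 20 go with a gain and equally with stronger binding there, and both stay open. For the other 3 cases a gain and a true cluster of binding cannot be told apart, because the width differences did not pass in either direction and no copy number was measured; no biological explanation was tested.

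The third pattern is the low sharing of ARNT regions on chromosome X. A late position of these regions in the ARNT list is argued against: given their places in 10 successive parts of the list, 29.6 shared regions were predicted and 17 seen, a difference of -12.6 (permutation p = 1e-05, one-sided). Few AHR regions on the chromosome may limit the partners, but over the other 22 chromosomes the shared fraction and the AHR density had a Spearman rho of only 0.12 (permutation p = 0.606) and a Pearson r of 0.21 (permutation p = 0.336; 0.37 without the 2 chromosomes farthest from the median density), which leaves this open. Sharing was lower on chromosome X than elsewhere in both parts of the ARNT list: 3 of 24 regions (12.5%) against 51.1% in the later 50% (Fisher's exact test, adjusted p = 4.39e-04), and 14 of 21 (66.7%) against 82.4% in the earlier 50%, which did not pass (Fisher's exact test, adjusted p = 0.0804). Whether the gap differs between these parts of the list was not tested.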
